A study of Mus musculus with 4 samples.

How the data were processed

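Total RNA from mouse mitral valve had been hybridised to 4 single-colour oligonucleotide arrays, 1 from WT, 2 from Het and 1 from Hom mice, with genotypes taken from the labels. The deposited values were intensities on a linear scale, 1 for each of 22690 probe sets. The software that made them was not given in the sources used here. From the values, each deposited array had a trimmed mean intensity of 150.1 after leaving out 2% of probe sets at each end, while medians were 63.7 in WT, 64.5 in Het replicate 1, 54 in Het replicate 2 and 65.5 in Hom.

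The log2 medians differed by 0.28, above the limit of 0.1 set before the data were examined, so each array was centred on the common median. Values were then floored at the 25th percentile of all values, an intensity of 19, and log2 transformed. A floor makes the fold of a gene below it a lower bound, and differences between dim genes are small or uncertain. Centring raised Het replicate 2 by 0.19 log2 units and lowered the others by 0.05 to 0.09.

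Probe sets were named through the platform annotation, with symbols updated by gene identifier. Of the probe sets, 20393 had 1 gene, 691 several and 1606 none; 20364 identifiers matched the reference table, and 64 control probe sets were left out. Genes were kept when the mean over the 4 arrays was at least the median of all probe sets, an intensity of 60.4, and each gene was represented by its probe set with the highest mean, which left 7319 genes. The Het arrays shared identical deposited values at 82 probe sets, so they were not duplicates.

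Genes were tested with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with Benjamini-Hochberg adjustment and a threshold of 0.05. A fit of 3 groups had 1 residual degree of freedom, from the Het pair, and a fit on the number of mutant alleles had 2. Counts of genes at least 2-fold apart needed no test. For 30 gene lists fixed before the data were examined, the median log2 difference of the members was set against 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these arrays; 28 lists had at least 3 members measured. Lists were tested for an allele trend with limma's camera, with a preset correlation of 0.01 and with an estimated one. To allow for the WT array that both Het differences share, 50 sets of 4 arrays were simulated with no change, independent genes and limma's spread of each gene. Lists of platelet, atrial, ventricular and non-matrix interstitial markers were added after the data were seen.

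The named genes followed a rule fixed before the data were examined. It took the 15 highest and 15 lowest Hom minus WT differences among genes with both Het arrays on the same side of WT. For Het against WT and Hom against Het it took the 10 highest and 10 lowest, with the Het arrays within 1 log2 unit of each other and on 1 side of the comparison array. Genes past a limma threshold came before others. In each list the 2 highest and 2 lowest Hom minus WT differences, and any member called, could be named.

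The fits were tested on simulated data with known changes. The noise of every simulated array, WT and Hom included, was resampled from the differences between the Het arrays. The rates below hold for that spread only. Genes changed 2-fold were called in 0% of cases in every comparison. The Het against WT test called 14% of genes changed 4-fold and 70% of those changed 8-fold. Among unchanged genes the false calls were 2 for Het against WT, 3 for Hom against WT, 0 for Hom against Het and 13 for the allele trend. A list of 25 genes shifted by 0.3 log2 units lay above the middle 95% of random lists in 15 of 20 draws, and 2 of 20 unshifted lists lay outside it.

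Alternatives were quantile normalization, no filter on mean level, a filter at the 75th percentile, no floor, the mean of all probe sets of a gene, leaving out each Het array, eBayes with trend and robust, other designs and a 1.5-fold size limit. The array scaling as deposited, and the estimated correlation with a Het array left out, were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.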

Results

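Gene expression was measured on 4 oligonucleotide arrays hybridised with total RNA from mouse mitral valve. One question of the design was how valve transcripts differ with the number of mutant copies of fibrillin-1, the glycoprotein that forms the extracellular microfibrils. The wild-type (WT) group held 1 array, the heterozygous (Het) group 2 arrays, and the homozygous (Hom) group 1 array; the mutant allele of the Hom label carries the C1039G change. Both Het labels leave out the substituted residue, and their allele was taken to be that of Hom. The labels did not say whether each array came from 1 animal or a pool, nor the age or sex, so a p-value measures only the spread between these arrays. WT and Hom had no replicates, and the number of arrays limits the precision of every value. Expression values are intensities after centring each array on the common median, given in the order WT, Het replicate 1, Het replicate 2 and Hom where 4 are listed. Fibrillin-1 itself was not analysed here, because none of the probe sets used carried its name.

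The WT and Hom arrays resembled each other more closely than the Het arrays did. Of 7319 genes compared, 66 were at least 2-fold apart between WT and Hom, against 677 between the Het arrays, which share 1 genotype label. Het replicate 2 was 2-fold apart from WT at 512 genes and from Hom at 521 genes, whereas Het replicate 1 was 2-fold apart from WT at 118 genes and from Hom at 88 genes. After quantile normalization the Het arrays were still 2-fold apart at 481 genes and WT and Hom at 77. After median centring the median gene was 0.19 log2 units higher in Het replicate 2 than in WT. That offset came with the centring, as it was -0.05 with the scaling as deposited and -0.004 after quantile normalization. Of the genes 2-fold apart from WT, 386 were higher and 126 lower in Het replicate 2, against 170 and 270 with the scaling as deposited. The medians and member counts of gene lists are therefore given relative to the median of all genes.

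Het replicate 2 also differed from the other arrays in markers of several cell types. The median of 33 cardiomyocyte markers lay 0.93 log2 units below WT in Het replicate 2 and 0.19 above it in Het replicate 1. The median of 23 macrophage markers was 0.67 above WT in Het replicate 2 and that of 6 erythroid markers 0.93 above, against -0.07 and -0.10 in Het replicate 1. Lyz2, the lysozyme of macrophages, read 304.8, 308.5, 981.1 and 319.6, and was chosen after its values were seen. The Actb 3' to 5' ratio, a measure of RNA integrity, was 3.04 in Het replicate 2 and between 2.16 and 2.25 on the other arrays. The geometric mean of 4 hybridisation controls was 597 in Het replicate 2 and between 1224 and 1711 on the others. Values of the Het arrays are therefore given separately where they differ.

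**Figure D1:**
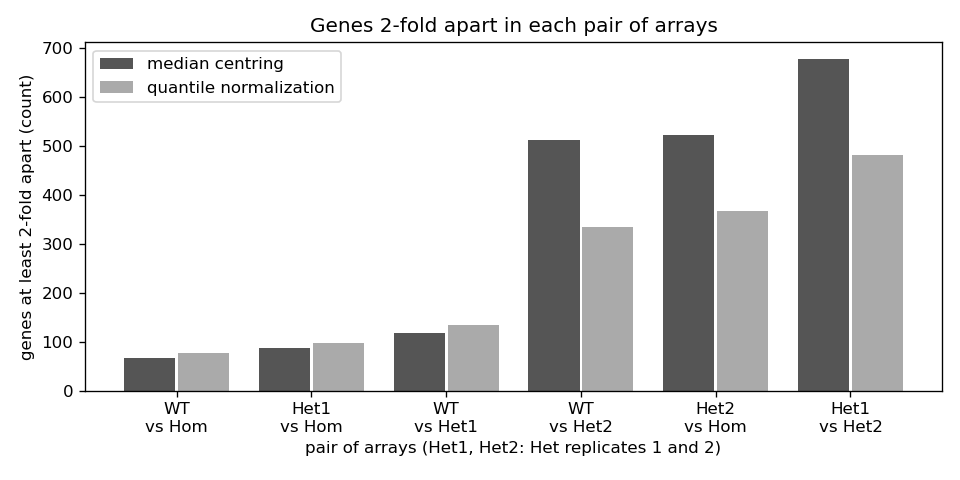
Number of genes at least 2-fold apart (of 7319) for each pair of the 4 arrays. The pairs that include Het replicate 2 lie between 512 and 677 genes, and the pairs without it between 66 and 118.

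The comparison of Hom with WT asked which transcripts differ when both fibrillin-1 copies are mutant. Among genes with both Het arrays on the same side of WT as Hom, Tbxa2r, the thromboxane A2 receptor, was higher in Hom by 1.65 log2 units (SE 0.53), with intensities of 38.3, 79.2, 73.9 and 120.5. Ccl2, a chemokine that attracts monocytes, was higher by 1.35 (SE 0.68), at 77.4, 134.1, 430.4 and 197.1. Tnmd, tenomodulin, a membrane protein of tendons and heart valves, was lower by 1.53 on the log2 scale, at 139.8, 70.5, 45.5 and 48.4. R3hcc1 gave the lowest difference, -2.05 (SE 0.55), at 194.4, 77.2, 111.3 and 46.9.

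The other genes with the highest Hom minus WT differences included Kcnq1, a cardiac potassium channel (1.40), the Wnt ligand Wnt7a (1.31), the Fc receptor gamma chain Fcer1g (1.28), Aldh1a3, an enzyme of retinoic acid synthesis (1.23), the sodium pump subunit Atp1b2 (1.19) and the mitotic kinase Nek2 (1.18). Nkain1 was at the floor in WT and reached 91.8 in Hom, at least 4.84-fold higher. The nucleoporin Nup50 (1.99), Cracr2b (1.66), Tmem87a (1.34) and Clca3a2 (1.18) were also among the 15 highest. Cklf (1.60) and Samhd1 (1.58) completed them, but their other probe sets gave Hom minus WT differences between -0.26 and -0.10 and between -0.84 and -0.14. The other probe set of Nup50 gave only 0.21. Among the 15 lowest were Nacc1 (-1.71), Ip6k1 (-1.45, with its other probe set at -0.33), Tcl1b3 (-1.39), Hivep2 (-1.37), Hip1r (-1.33), the filamin-binding protein Rflnb (-1.29), the kinase Hipk2 (-1.24) and Rcor2 (-1.21). Hebp1 (-1.18), Ap1b1 (-1.17), the checkpoint protein Rad9a (-1.10), Bmyc (-1.07) and the metallothionein Mt1 (-1.05) were the remaining ones. Of these 30 genes, 19 stayed below an intensity of 200 on every array, and 4 (Samhd1, Tcl1b3, Hipk2 and Mt1) were read by probe sets of a type that can bind several transcripts.

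Of the 66 genes 2-fold apart between WT and Hom, 32 were higher and 34 lower in Hom, and 48 had both Het arrays on the same side of WT (27 higher, 21 lower). The balance depends on the scaling. With the scaling as deposited 41 were higher and 29 lower in Hom, and 34 and 19 of these had both Het arrays on the same side. Of the 66, 57 had a mean intensity below 200, as did 53.4% of all genes compared. No gene passed limma's test at an adjusted p of 0.05, where 32 passed an unadjusted 0.05 and 366 would by chance. That test took its spread from the Het pair alone and assumed that the lone WT and Hom arrays vary like it. The log2 differences had an SD of 0.57 between the Het arrays and 0.32 between WT and Hom. The spread used may therefore be too wide for WT and Hom, and a count below that by chance does not show that the genotypes are alike. In simulated data, with the noise of every array drawn from the Het pair, the test called 20% of genes changed 4-fold in Hom and 84% of those changed 8-fold. Sex-linked transcripts also differed on the Hom array, although Xist and the Y-linked Eif2s3y both read above the floor on every array. The sex behind each array therefore stays open. Xist, transcribed from the inactive X chromosome, was lowest in Hom with both probe sets kept, at 889.2, 859.8, 1069 and 564.1 and at 422.4, 346.5, 477.6 and 172.6. The Y-linked Eif2s3y was highest in Hom, at 93.2, 115.3, 129.8 and 154.8.

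**Figure D2:**
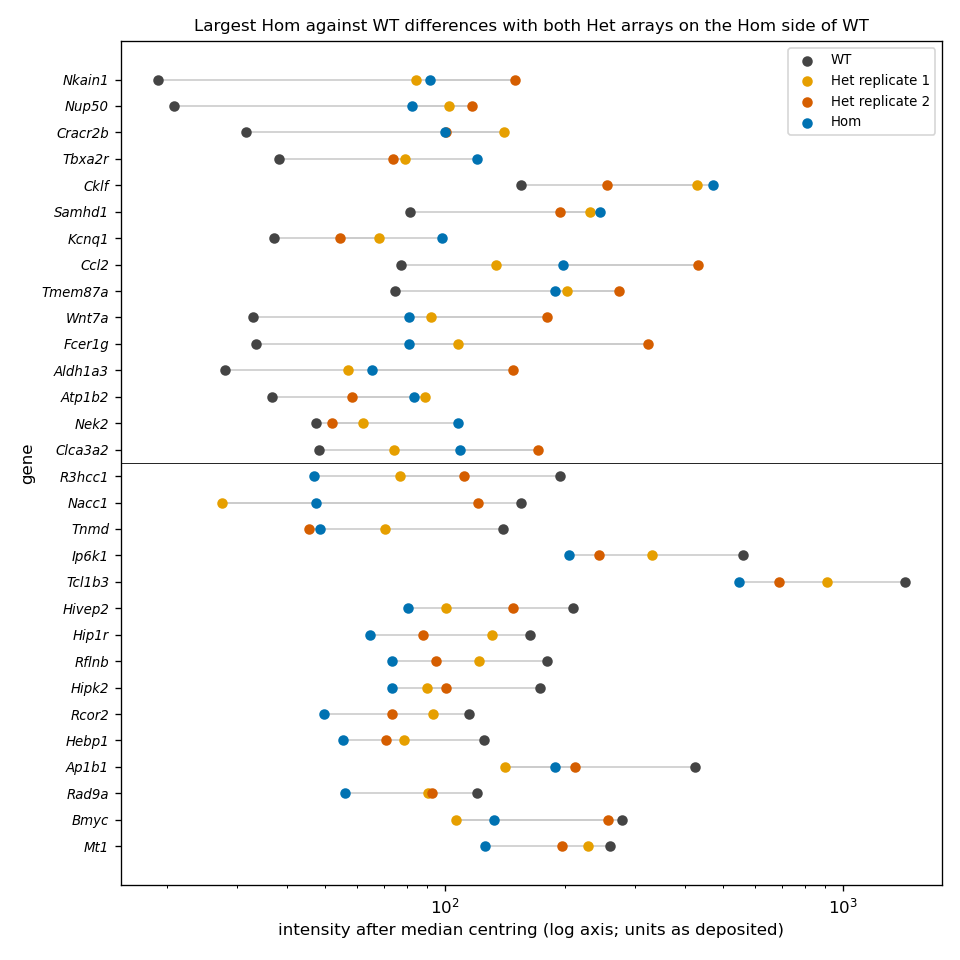
Intensity on a log axis of the genes with the highest and lowest Hom minus WT differences, 1 point per array. Tbxa2r runs from 38.3 in WT to 120.5 in Hom and Tnmd from 139.8 to 48.4, with the Het arrays on the Hom side of WT.

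List medians for Hom minus WT ran from -0.26 to 0.29 log2 units over 28 lists. The TGF-beta response list holds genes chosen as responding to the growth factor that microfibrils help to sequester. Its median lay 0.09 log2 units above WT, at the 98th percentile of random lists of matched expression, and 0 of its 32 members were 2-fold apart. The list moved with the settings, to 0.04 with no filter, 0.15 with the mean of all probe sets and 0.14 without Het replicate 2. Its highest members were Tnc, the matrix protein tenascin C (135.7 in WT and 249.6 in Hom), and the protease inhibitor Timp1 (995.9 and 1546), and its lowest Skil (708.4 and 395.8) and Vegfa (170.2 and 102.6). The 24 TGF-beta ligands, receptors and transducers had a median of -0.04, at the 26th percentile. The 7 antigen presentation genes had a median of 0.27 with 6 members above WT, including the class II genes H2-Ab1 (64.7 in WT and 145.4 in Hom) and H2-Eb1 (195.7 and 334.5). That median was unstable, at 0.499 without Het replicate 1 and 0.497 without Het replicate 2, with the filter redone. The valve interstitial and fibroblast markers (-0.19, 19 genes) and the osteochondrogenic genes (-0.26, 8 genes) lay below the middle 95% of random lists, but the first was -0.04 after quantile normalization and the second 0.08 with the filter at the 75th percentile. The immediate early and heat shock genes (0.12), oxidative phosphorylation genes (0.05), cardiomyocyte markers (0.06) and adipocyte markers (0.23) lay above it. After quantile normalization the oxidative phosphorylation and cardiomyocyte medians were 0.12 and 0.21, and with no filter the adipocyte median was 0. In all, 8 of 28 lists lay outside the middle 95% for Hom minus WT, where 1.4 would if genes were independent, and 13 did between the Het arrays of 1 genotype. Adjusted over the list alone, 0 genes passed limma's test for Hom against WT in any list, as over all genes.

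The comparison of Het with WT asked what differs with 1 mutant copy. Ppbp, a chemokine precursor stored in platelets, was 10.4-fold higher in Het, at 71.4, 534.7, 1025 and 82.6 (log2 difference 3.37, SE 0.50, limma adjusted p = 0.0444, higher in 2 of 2 Het arrays). It was the only gene past the threshold, where 84 genes passed an unadjusted 0.05, 366 would by chance, and 5 of 8 other settings called none. In simulated data, with noise drawn from the Het pair, the same test called 2 unchanged genes. No matrix gene passed over all genes. Mfap4, a microfibril-associated protein, was at 869.7, 345.7, 274.5 and 512.1 (2.82-fold lower, SE 0.47 on the log2 scale), and Eln, which encodes elastin and was chosen after its values were seen, at 3725, 1932, 1717 and 3071.

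The list of elastic fibre and microfibril genes had a median 0.39 log2 units below WT in Het replicate 1 and 0.53 below in Het replicate 2, and 12 of its 13 members were below WT in both; in Hom 10 of the 13 were below WT, with a median of -0.09. The 23 collagen genes gave -0.27 and -0.54, with 16 below WT in both arrays. The 21 proteoglycan and hyaluronan genes gave -0.19 and -0.48, with 12 below in both. Their value in the mean of the Het arrays, -0.43, became -0.21 with means in place of medians and -0.28 after quantile normalization. The 18 valve and endocardial cushion transcription factors gave -0.21 and -0.51, with 13 below in both. With Het replicate 2 left out and the filter redone, the proteoglycan list was at -0.15 and the transcription factors at -0.18. All 4 lists lay below the middle 95% of random lists in each Het array, the proteoglycan list narrowly so in Het replicate 1 (percentile 2.16). However, both differences subtract the same WT array. In 50 simulations with a shared WT array and no changed genes, at most 1 of 28 lists did so; genes were drawn independently there, and genes that vary together would give more. Compared with Hom in place of WT, 3 of the 4 lay outside the middle 95% for both Het arrays, with Hom higher; the proteoglycan list lay at percentile 80.6 for Het replicate 1. The Het arrays also differed from each other, Het replicate 2 lying lower by 0.36 for the elastic fibre list and by 0.25 for the transcription factors. Interstitial and fibroblast markers were at -0.18 and -0.57 and osteochondrogenic genes at -0.26 and -0.92, inside the middle 95% in Het replicate 1 and below it in Het replicate 2. Matrix proteases and inhibitors were inside it in both, at -0.08 and -0.08. Tbx5, a transcription factor of heart development, read 162.8, 23.3, 57.9 and 161, and was lower in Het with a limma adjusted p of 0.0214 over the list alone, but did not pass over all genes; for Hom against Het the same test gave an adjusted p of 0.0228 over the list alone. The 41 cell cycle genes had medians of 0.16 and 0.34, with 27 above WT in both arrays; the helicase subunit Mcm2 read 262, 493.5, 638.2 and 400.1. Fcer1g, at 33.5, 107.4, 323.6 and 81.2, had a limma adjusted p of 0.014 for Het against WT over the macrophage list alone and did not pass over all genes. Adjustment over 1 list does not cover the 30 lists and 3 comparisons. Apoptosis genes were 0.09 and 0.16 above WT, each inside the middle 95%, while the mean of the Het arrays gave 0.17, above it (percentile 98.85). In all, 14 of 28 lists lay outside the middle 95% for the mean of the Het arrays minus WT, 9 for Het replicate 1 and 13 for Het replicate 2.

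Other lists rested on Het replicate 2. The endothelial median was -0.43 in Het replicate 2 and -0.02 in Het replicate 1. The mean of the Het arrays put the TGF-beta response list 0.18 above WT, but without Het replicate 2 its median was -0.04. Antigen presentation genes went opposite ways, at 0.84 in Het replicate 2 and -0.33 in Het replicate 1, each outside the middle 95%, and the mean of the Het arrays, 0.13, lay inside it.

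Further genes high in both Het arrays were Nkain1, Nup50, Wnt7a, Cracr2b, Tmem87a, Cby1 (1.64), the smooth muscle actin Actg2 (1.54) and the glucose transporter Slc2a3 (2.84-fold). Samhd1 was high by 1.38, but its 3 other probe sets gave Het minus WT differences between -0.73 and -0.18. Nup50 was high by 2.39, with its other probe set at 0.54. The probe sets of Slc2a3, Ksr1 and Fmo2 are also of a type that can bind several transcripts. Low in both were the kinase scaffold Ksr1 (-1.47), the magnesium transporter Slc41a3 (-1.36, with its other probe set at -0.40), Tnmd (-1.30), Ap1b1 (-1.29), Tle5 (-1.26), Chmp1a (-1.24), Leng8 (-1.20), Fmo2 (-1.16, with its other probe set at -0.67) and the C-type natriuretic peptide Nppc (-1.12). In all, 21 genes were at least 2-fold higher and 9 at least 2-fold lower than WT in both Het arrays. These counts are not corrected for the higher median gene of Het replicate 2; they were 21 and 12 after quantile normalization and 18 and 17 with the scaling as deposited, so the excess of higher genes depends on the scaling.

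**Figure D3:**
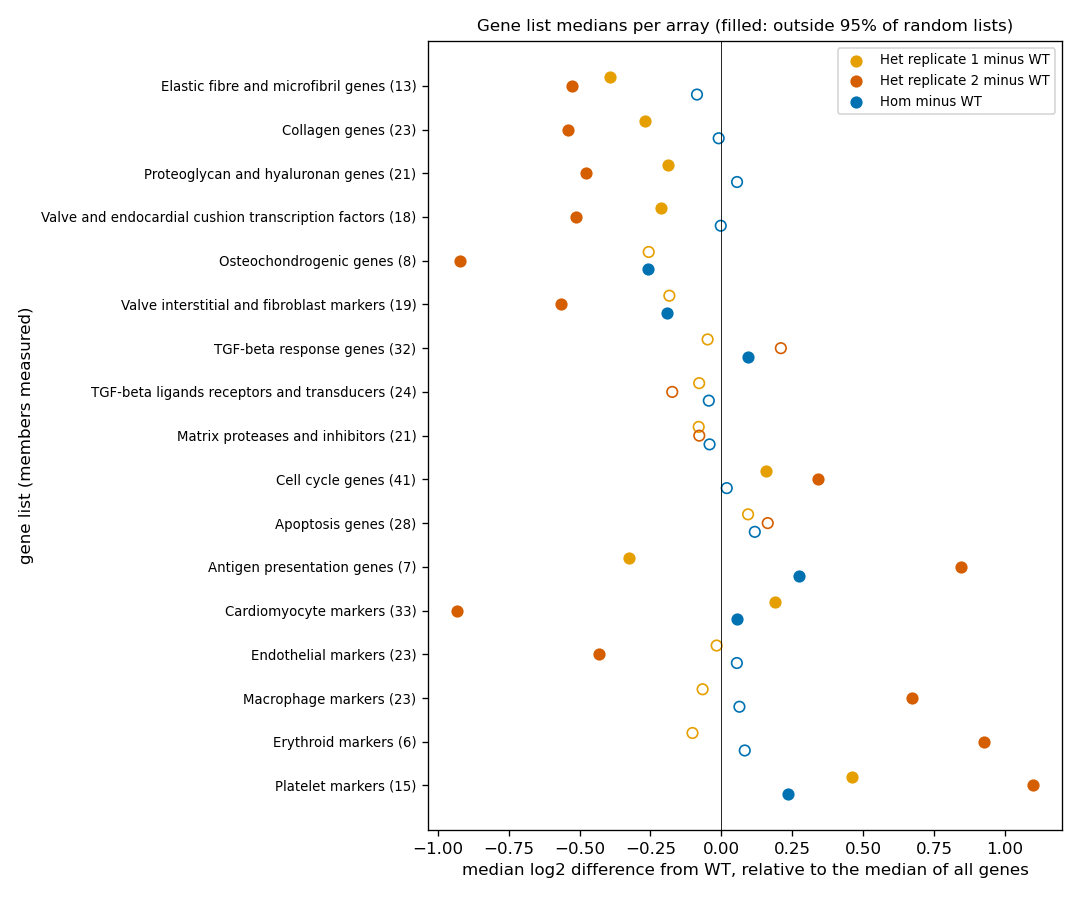
Median log2 difference from WT of each gene list, relative to the median of all genes, for Het replicate 1, Het replicate 2 and Hom; filled points lie outside the middle 95% of 10000 random lists of matched expression. Elastic fibre genes lie at -0.39 and -0.53 in the Het arrays and at -0.09 in Hom.

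The comparison of Hom with Het asked what differs between 2 mutant copies and 1. Col12a1, a fibril-associated collagen, was higher in Hom than in both Het arrays, at 71, 58.9, 55.8 and 274.4 (log2 difference 2.26, SE 0.46). Its limma adjusted p was 0.00398 over the collagen list alone and 0.317 over all genes; it rests on 1 Hom array, with the spread taken from the Het pair. Cxcl13, a B cell chemokine, was higher by 1.25, at 97.6, 80.5, 63 and 168.9. Ppbp was lower by 3.16 log2 units (limma adjusted p = 0.0931), and Pf4, platelet factor 4, read 935.1, 1341, 2286 and 679.6. Collagen genes were above both Het arrays in Hom at 18 of 23 members, and elastic fibre genes at 8 of 13 with none below both. Cell cycle genes were below both Het arrays at 23 of 41 members. For Hom minus the mean of the Het arrays, 14 of 28 lists lay outside the middle 95%.

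Leng8 (1.69), Chmp1a (1.23), Clstn3 (1.22), Slc41a3 (1.22, with its other probe set at -0.22), Clec16a (1.11), Cmya5 (1.10), Ptpn21 (1.09) and the nucleotide receptor P2ry4 (1.07) were also higher in Hom. Btbd2 (-2.42), Ica1 (-2.06), Cdca7l (-1.62), Usp39 (-1.60, by a probe set that can bind several transcripts, and -0.24 by its other), the deacetylase Sirt2 (-1.30), Brwd1 (-1.28, with its other probe set at -0.41), Slc2a3 (-1.28) and the replication protein Rpa2 (-1.26) were lower. Relative to both Het arrays, 9 genes were at least 2-fold higher in Hom and 14 at least 2-fold lower, against 10 and 12 after quantile normalization and 13 and 10 with the scaling as deposited. No gene passed limma's adjusted threshold in the main setting, and fewer genes passed an unadjusted 0.05 than would by chance.

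The series of 0, 1 and 2 mutant alleles asked whether expression follows allele number. Both Het arrays lay between WT and Hom at 8.09% of genes. By chance 16.7% would if the 4 arrays were exchangeable, but the distance of Het replicate 2 from the others would lower the share. The step from WT to one Het array and the step from the other Het array to Hom, which share no array, correlated across genes at a Pearson r of 0.05 and 0.03; genes are not independent replicates. In limma's trend fit 0 genes passed the adjusted threshold and 43 passed an unadjusted 0.05, where 366 would by chance. Of 28 lists, 0 passed limma's camera test for a trend (lowest adjusted p = 0.256 with a preset correlation, adjusted p = 0.983 with an estimated correlation). Without either Het array in turn, the antigen presentation list passed with the preset correlation, at adjusted p = 0.000134 without Het replicate 1 and 0.0084 without Het replicate 2. With an estimated correlation it did not pass in either case (adjusted p = 0.970 and 0.988).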

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

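The array scaling as deposited, and the estimated correlation with a Het array left out, were chosen after seeing the data; the other alternatives were planned. The 70 named gene results kept their direction in all 472 values that could be recomputed. This is a weak check, because the genes had been chosen for large differences on these same arrays. The Hom minus WT differences also do not use the Het arrays that were left out. Not every named gene was kept in each setting, least of all with the filter at the 75th percentile. No paired analysis was possible because WT and Hom have 1 array each and the groups compared share fewer than 2 replicate numbers. Without a Het array the 3-group fit has no residual degrees of freedom, so those tests were not run. The number of genes past the limma threshold stayed 0 for Hom against WT in 8 other settings and for the allele trend in 9. For Het against WT it was 1 and became 4 after quantile normalization, and 0 with the 3 mutant arrays against WT, with no filter, with no floor, with the mean of all probe sets and with the scaling as deposited. For Hom against Het it was 0 and became 4 after quantile normalization, 1 with eBayes with trend and robust, and 1 with the filter at the 75th percentile. Counts of genes 2-fold apart moved with the filter and size limit by construction. For Hom against WT, Het against WT and Hom against Het they were 308, 224 and 198 at 1.5-fold, 251, 142 and 132 with no filter, and 11, 4 and 3 with the filter at the 75th percentile; the last was 14 with the mean of all probe sets. WT and Hom were 2-fold apart at 365, 14 and 41 genes with no filter, with the filter at the 75th percentile and with the mean of all probe sets, and the Het arrays at 1151, 373 and 398. The correlations of independent steps were 0.104 and 0.0910 with the filter at the 75th percentile. The number of lists outside the middle 95% for Hom minus WT was 4 with means in place of medians and 5 with the filter at the 75th percentile. Where a smaller or larger set of genes does not show it, the cause was not tested.

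Leaving out each Het array in turn gave 109 to 512 genes for Het against WT and 81 to 525 for Hom against Het, since 1 array then has to differ in place of both. Lists outside the middle 95% numbered 6 to 13 for Het minus WT and 9 to 15 for Hom minus Het, against 14 for each with both Het arrays, the lower ones without Het replicate 2 and with centring, floor and filter redone on 3 arrays. Here 1 list, antigen presentation, passed the allele trend in both cases with the preset correlation but not with an estimated one (adjusted p = 0.970 without Het replicate 1 and 0.988 without Het replicate 2). The correlation of independent steps needs both Het arrays and was not run without one. Of 846 recomputed list medians 76 changed sign, of which 60 had lain inside the middle 95% in the main setting and 16 outside it. Of the 16, 11 changed sign without Het replicate 2, so that their direction rests on that array. Leaving out each Het array in turn gave, for Het minus WT, -0.0351 to 0.242 for TGF-beta response genes, -0.935 to 0.188 for cardiomyocyte, -0.0279 to 0.607 for macrophage and -1.32 to 0.183 for ventricular muscle markers. For Hom minus Het it gave -0.0261 to 0.711 for osteochondrogenic, -0.135 to 0.272 for oxidative phosphorylation, -0.0406 to 1.05 for cardiomyocyte, -0.0803 to 0.347 for endothelial, -0.855 to 0.267 for erythroid, -0.545 to 0.201 for macrophage and -0.106 to 1.34 for ventricular muscle. The atrial muscle median for Hom minus Het was -0.283 with both Het arrays. With 1 left out it ran from -0.0179 to 0.139, positive without Het replicate 1, so the main value was not reproduced. It was 0.0716 with means in place of medians. The oxidative phosphorylation median was -0.027 for Hom minus Het with no filter and -0.00798 for Hom minus WT with the mean of all probe sets. The osteochondrogenic median for Hom minus WT was 0.0809 with the filter at the 75th percentile. Apart from the left-out array, the cause was not tested.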

Other observations

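All tests of explanations given here were chosen after the results were seen, as were the platelet, atrial, ventricular and non-matrix interstitial lists. The 15 platelet markers were all higher in the mean of the Het arrays than in WT, and 13 were above WT in both, with 2 split between them. Their medians were 0.46 log2 units above WT in Het replicate 1, 1.10 in Het replicate 2 and 0.23 in Hom. The Hom median was 0.07 without Het replicate 2, 0.09 after quantile normalization and 0.03 with no filter. Because Ppbp and Pf4 had been seen before the list was made, it is not independent evidence. Clec1b, a platelet receptor, read 23.4, 135.5, 362.5 and 45.8 in WT, Het replicate 1, Het replicate 2 and Hom. Plek read 88.2, 205.6, 522.3 and 175. In the mean of the Het arrays, Clec1b lay 3.25, Plek 1.89 and Gp1bb 1.70 log2 units above WT, and F13a1, the lowest of the list, 0.28. A test adjusted over this list alone would not be valid, because the list was made after Ppbp had been seen.

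Lists not described so far lay inside the middle 95% of random lists for Hom minus WT. Their medians were -0.04 for matrix proteases and inhibitors, 0.12 for apoptosis, -0.06 for interferon response, -0.13 for ribosomal proteins, 0.07 for smooth muscle, -0.004 for skeletal muscle and 0.05 for endothelium. They were -0.12 for granulocytes and mast cells, 0.13 for lymphocytes, 0.08 for melanocytes, -0.17 for Schwann cells and neurons and 0.29 for epicardium and epithelium. Of the angiotensin system 2 genes were measured, Ace at 175.3 in WT and 136.2 in Hom and Cma1 at 157.2 and 132.5. The atrial list gave -0.29, -0.27 and -0.19 in Het replicate 1, Het replicate 2 and Hom, and the ventricular list 0.19, -1.32 and 0.07. The atrial medians hide members that moved apart, and the mean of the Het arrays gave 0.10. Of its 9 members, 5 were split between the Het arrays, 1 was above WT in both and 3 were below.

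Het replicate 2 stood apart from the other arrays. Array-wide scaling is argued against as the whole cause, since 481 genes were 2-fold apart between the Het arrays after quantile normalization, against at most 134 in pairs without Het replicate 2. With less heart muscle alone, macrophage and valve interstitial markers should move alike. Against the mean of the other 3 arrays, macrophage markers lay 1.02 log2 units above valve interstitial ones (interval over genes 0.706 to 1.58). This speaks against that explanation for this 1 array only. Genes that vary together are not replicates, and both lists had been seen before the test was chosen. Lower RNA quality stays open, and both 3' to 5' ratios were highest in Het replicate 2, as it would give. That of Actb was 3.04 against at most 2.25, and that of Gapdh 4.65 against 3.19 to 4.18 on the others. A different dissection or animal may also account for it and was not tested. The hybridisation controls were dimmer on this array too, at a geometric mean of 597 against 1224 to 1711 on the others. What that reflects was not tested either.

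Platelet genes were higher in both Het arrays. More residual whole blood in Het replicate 1 is argued against, because its erythroid median was -0.102 relative to WT. The interval over genes of that 1 array, -0.383 to 0.215, ends below the 0.433 of the 13 platelet markers other than Ppbp and Pf4. That median has no interval, and its members ran from -0.41 (Selp) to 2.54 (Clec1b) log2 units from WT. The 6 erythroid genes are not replicates, so this speaks against whole blood for that 1 array only. In Het replicate 2 the erythroid median was 0.926 above WT, which is in line with more whole blood there. Platelets held on the valve, in clots or on its surface, may differ with genotype or with dissection, and neither was tested.

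The elastic fibre, collagen and proteoglycan lists were lower in both Het arrays, and in Hom their medians were -0.09, -0.01 and 0.06, although 10 of 13 elastic fibre genes lay below WT there. Dilution of the whole valve by added muscle stays open in Het replicate 1: elastic fibre genes lay apart from endothelial ones by -0.376 (interval -0.729 to -0.0322), but cardiomyocyte markers were above the middle 95% and muscle brings endothelium of its own. In Het replicate 2 the same difference was -0.0949 (interval -0.497 to 0.298) and the erythroid list was high, as dilution by blood would give. Other lists went the other way there. Against the mean of the other 3 arrays, smooth muscle markers lay 0.36 log2 units higher relative to all genes, with 7 of 12 members higher. Melanocyte markers lay 0.29 higher, with 5 of 9 members higher. Dilution by blood alone would not give such rises, so it stays open as a partial cause only. A smaller share of interstitial cells cannot be told apart from lower expression per cell, since the non-matrix interstitial list, at -0.457 in the mean of the Het arrays, lay below the middle 95% in Het replicate 2 but at percentile 7.12 in Het replicate 1. An effect that is smaller with 2 mutant copies than with 1 stays possible and untested, as do age, sex and dissection.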
